A study of Mus musculus with 18 samples.

How the data were processed

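H3K27me3 was measured by CUT&Tag in single headfolds of Gulo-/- mouse embryos at embryonic day 8.5, with one headfold per reaction per the labels' protocols. Of the 18 samples in the series, the peak lists of 12 H3K27me3 libraries were used, 3 for each background (129 or B6) and diet (with or without vitamin C), each group with 2 female and 1 male embryos per the labels. The 4 IgG control samples and 2 further H3K27me3 samples of B6 were not analysed here. B6 replicates keep the numbers 1, 2 and 4. Library numbers run with the background, and the 3 B6 embryos with vitamin C share 1 pregnancy code.

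The tools cutadapt, Bowtie2, Picard and SEACR and the genome build mm10 are named per the submitters' processing notes, and their versions and settings are not given in the sources used here. Whether the IgG libraries or a numeric threshold set the peak calls is likewise not given in the sources used here. Each deposited list holds the peaks of a single library in 6 columns, with the position, the total signal and the maximum signal of each peak. The signal values were deposited by the authors as whole numbers with no scaling to a common depth visible in the values. They were used only to rank or filter peaks within a list. The number of reads per library is not part of the lists, so the precision that depth gives to each list is unknown, and list lengths can follow depth as well as biology.

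Peaks of all libraries (31753 in total) were merged by overlap of at least 1 bp into regions, and regions called in at least 2 libraries (3533) were kept. Gene positions came from the RefSeq genes of GRCm38.p6, the assembly mm10 stands for. This table carries no strand, so the planned window around the transcription start was replaced by 1 kb around either end of the gene. A gene was called marked where at least 1 bp of a peak lay within that window. Windows of 0 and 2.5 kb were tried as alternatives, and peaks anywhere in the gene and peaks at both ends were added as alternatives once the gene table was known to lack strand. Coordinates are 1-based. The 16 gene lists were written by hand before the data were examined, as were the comparisons, their tests and the alternatives other than those named as added. The list symbols Cart1, Jmj and Nesp (3 in total) had no match in the gene table and were left out.

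Peak number, covered length and number of marked genes were compared on a log2 scale by exact permutation of diet labels within background (400 relabellings, smallest possible p 0.005) or within one background (20 relabellings, smallest possible p 0.1). The diet effect in 129 minus that in B6 and the comparison of backgrounds used the same number of relabellings. Similarity of peak sets was the Jaccard index in bp, tested on one side by the same permutation. The X chromosome share of covered length was compared between the labelled sexes within background (smallest possible p 0.00444). Each region was tested for diet by exact permutation within background with Benjamini-Hochberg adjustment. Gene lists were tested for diet by the same permutation of the share of marked members, and for genes marked in at least 10 of 12 libraries by Fisher's exact test against all other protein-coding genes, both adjusted over the 16 lists. The threshold was 0.05. The region test was run on simulated data in which 200 of 3533 regions were present in every library with vitamin C and absent without it. Each of these has the smallest possible p by set-up, so recovery of 100% at unadjusted p under 0.05 was fixed in advance. It does not bear on partial effects. After adjustment 0% were recovered, which depends on the number of changed regions. Of unchanged regions 0.15% were called before adjustment.

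The genes named were fixed by rule. For each background and diet direction they are up to 10 genes marked in all 3 libraries of one diet and 0 of the other, by largest mean peak width. For diet over both backgrounds, and for background, they are the 10 genes per direction with the largest difference in marked libraries. For sex they are the 10 X-linked genes with the largest excess in females. The 10 widest regions called in all 12 libraries and, per gene list, the members with the largest difference between diets complete the rule. A few genes that the rule names or that belong to the lists are not reported here. Genes and regions named outside this rule are stated as chosen after their values were seen. Alternatives were peaks of at least 1 kb, peaks at or above their list's median maximum signal, autosomes only, peaks less than 5 kb apart joined, equal lists of the 748 peaks with the largest total signal, other scales and permutation strata, and each library left out in turn. Omission of the 2 libraries with a median peak width under 2 kb was also added, after the lists had been seen. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, bedtools 2.31.1 and Matplotlib 3.10.9.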

Results

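H3K27me3, the histone mark laid down by Polycomb repressive complex 2, was profiled by CUT&Tag in mouse headfolds, the anterior part of the embryo from which the brain arises, at embryonic day 8.5. CUT&Tag tethers a transposase to an antibody and sequences the DNA cut around the mark. All embryos were Gulo-/- and so lacked L-gulonolactone oxidase, the last enzyme of vitamin C synthesis. They were of the 129 or the B6 background, and their dams did or did not receive vitamin C at 3.3 g/l in the drinking water. The design asks whether vitamin C withdrawal changes the distribution of the mark, and whether this differs between the backgrounds. Peak lists of 12 libraries were analysed, 3 per background and diet, each group holding 2 female and 1 male embryos. The 3 B6 embryos with vitamin C all carried the same pregnancy code. The lists held 748 to 4726 peaks and covered 3.58 to 31.7 Mb of the mm10 genome. Sequencing depth was not part of the lists, so it is unknown, and no signal values were compared between libraries. In what follows a gene is called marked in a library where a peak lies within 1 kb of either of its ends, and 572 to 3387 genes were marked per library.

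The 4 Hox clusters, which encode the transcription factors that pattern the trunk and hindbrain, carried the broadest H3K27me3 domains shared by all embryos. The widest region called in all 12 libraries spanned the Hoxc cluster (chromosome 15, 102901040 to 103074009, 173.0 kb). It was followed by the regions over Hoxb (chromosome 11, 96241324 to 96378448, 137.1 kb), Hoxa (chromosome 6, 52145893 to 52279224, 133.3 kb) and Hoxd with Evx2 (chromosome 2, 74642864 to 74767960, 125.1 kb). Of the 39 Hox genes, 39 were marked in at least 10 libraries and 25 in all 12. Peaks covered a median of 97.9% of the Hoxc cluster over the 12 lists, with 26.9% in the sparsest list, and 91% of Hoxa, 88.2% of Hoxd and 72.3% of Hoxb. The next widest regions lay over Mir9-3 and its host transcript Mir9-3hg, a locus of the neural microRNA miR-9 (chromosome 7, 79492255 to 79563179, 70.9 kb), and over Zic1 and Zic4, zinc finger genes of the dorsal neural tube (chromosome 9, 91347086 to 91412748, 65.7 kb). Further regions covered Unc13a, Jak3, Insl3, B3gnt3 and part of Fcho1 (61.9 kb), Rhbg and the microRNA gene Mir9-1 (61.3 kb), Nfix and Dand5 (60.2 kb), and Plekhg5, Tnfrsf25, Espn and Hes2 (59.1 kb). In all, 3533 regions were called in at least 2 libraries, and 438 of them (12.4%) in all 12.

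Beyond Hox, lists of developmental regulators of all germ layers held a larger share of genes marked in most embryos than the rest of the genome. Neurogenic and neuronal differentiation genes were marked in at least 10 libraries for 26 of 36 members, among them Neurog1 and Neurog2, which start neuronal differentiation, and Pou4f3. Regulators of heart and vessels (17 of 23, such as Nkx2-5, Hand2 and Tbx5), of mesoderm, somite and muscle (17 of 25, such as Myod1, T and Pax1) and of endoderm (15 of 21, such as Foxa2, Cdx2 and Pdx1) were also marked. Further lists were those of anterior neural plate and brain patterning genes (24 of 34), dorsal neural tube and neural crest genes (20 of 30), ventral neural tube and floor plate genes (10 of 17) and placode and surface ectoderm genes (13 of 24). Of the 21887 protein-coding genes tested, 4.73% were marked in at least 10 libraries. Each of these lists and the Hox list stood above that background by Fisher's exact test (largest adjusted p = 1.38e-09, Benjamini-Hochberg over 16 lists). Genes are not independent replicates in this test, and neighbouring members can share a domain.

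Within the anterior neural list the mark was unevenly spread. Six3, Pax6, En1, En2, Gbx2, Emx2 and Wnt1 were marked in at least 10 of the 12 libraries, whereas Sox2 and Zic5 were marked in 2, Irx3 in 2, Otx2 in 3 and Hesx1 in 0. Sox2, Otx2 and Hesx1 are transcription factor genes of the early anterior neural plate. Other transcription factor genes of the same list, such as Rax, Lhx2, Otx1 and Six6, were marked in at least 10 libraries, so these 3 do not stand for a class. In the dorsal neural tube and neural crest list, Msx1, Foxd3, Olig3 and Atoh1 were marked in at least 10 libraries and Sox9 in 0. The genes named in this paragraph and the one before it were chosen after their values were seen.

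Imprinted genes were a further list above the background, with 6 of 38 coding members marked in at least 10 libraries (15.8%, Fisher's exact test, adjusted p = 0.0134). The members were Ascl2, Dio3, Dlk1, Kcnq1, Rasgrf1 and Slc22a3, and Igf2 was marked in 9 libraries. With peaks required at both gene ends the call was lost (2 of 38, Fisher's exact test, adjusted p = 0.114). The other 6 lists did not stand above the background. Housekeeping genes were marked in at least 10 libraries for 0 of 30 members, vitamin C transport and dependent enzymes for 0 of 32, and DNA methylation and demethylation enzymes for 0 of 14. Tet1 and Tet3, dioxygenases that use vitamin C as a cofactor, were marked in 0 libraries, Tet2 in 2, and the deleted gene's own locus, Gulo, in 0. Of 35 germline genes under DNA methylation control, only Tdrd6 reached 10 libraries. Neural tube closure genes reached 2 of 33, Pax3 and Alx1, and Grhl3, needed for closure of the spinal neural tube, was marked in 9 libraries. Among Polycomb subunits, Cbx8 was marked in 12 libraries and Phf19 in 10, and the call for this list (2 of 30, Fisher's exact test, adjusted p = 0.764) was gained with a window of 2.5 kb (5 of 30, adjusted p = 0.0321).

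**Figure D1:**
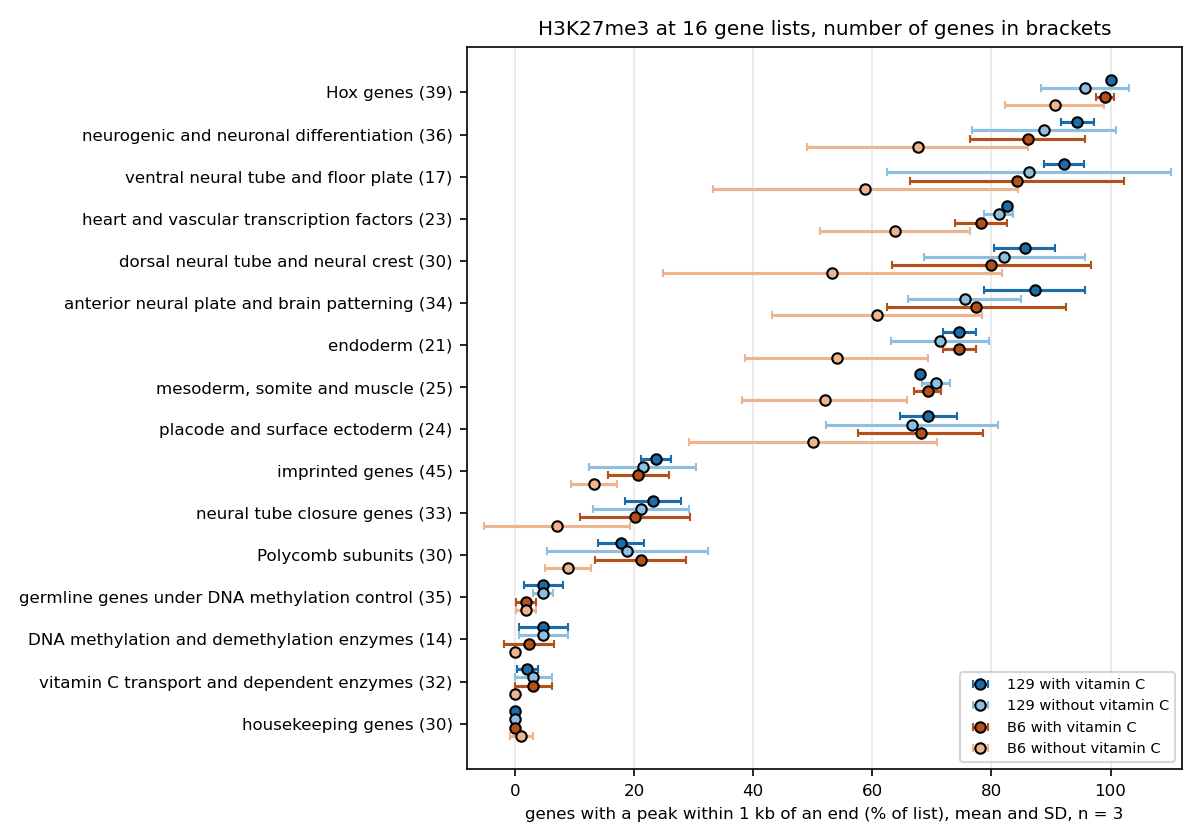
Share of the genes of each of 16 lists that had a peak within 1 kb of an end (horizontal axis, %), as the mean of 3 libraries with its SD, for each background and diet. Hox genes lay above 90% in every group and housekeeping genes at or near 0, and in most developmental lists the B6 group without vitamin C had the lowest mean.

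The first comparison was of embryos without against embryos with vitamin C. Over both backgrounds neither the number of peaks nor the amount of marked chromatin passed the test for a difference between the diets. In B6 the 3 libraries with vitamin C each held more peaks than the 3 without it, by as little as 2397 against 2395, and in 129 the groups overlapped. In 129, libraries without vitamin C held 2513.3 ± 979.2 peaks (SD, n = 3) and those with it 2416.3 ± 560.2. In B6 they held 1840.3 ± 946.0 without and 3814.3 ± 1244.1 with vitamin C. This was 0.443-fold on geometric means (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 can give). That test takes embryos as independent, but the 3 B6 embryos with vitamin C shared 1 pregnancy code. The log2 difference in B6 of -1.17 became -0.62 without B6 without vitamin C replicate 2. Over both backgrounds the log2 difference was -0.59 (0.664-fold, p = 0.17, exact permutation of diet labels within background, 400 relabellings, smallest possible p 0.005). Covered length (0.57-fold, p = 0.155) and marked genes (0.654-fold, p = 0.175) gave the same direction in the same exact test. With equal lists the log2 difference in marked genes was -0.21, against -0.61 with full lists. For peak number over both backgrounds it was -0.59 with embryos of one timed pregnancy averaged (exact permutation p = 0.362, 80 relabellings). Without B6 without vitamin C replicate 2 it was -0.31 (exact permutation p = 0.325). The diet effect on peak number in 129 minus that in B6 was 1.17 on the log2 scale (exact permutation of diet labels within background, p = 0.2). These relabellings stand for no diet effect in either background, so a low p alone would not show that the backgrounds differ. Of single omissions, only that of 129 without vitamin C replicate 2 took it past the threshold (1.55, exact permutation p = 0.02). Without B6 without vitamin C replicate 2 it was 0.61 (exact permutation p = 0.345).

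**Figure D2:**
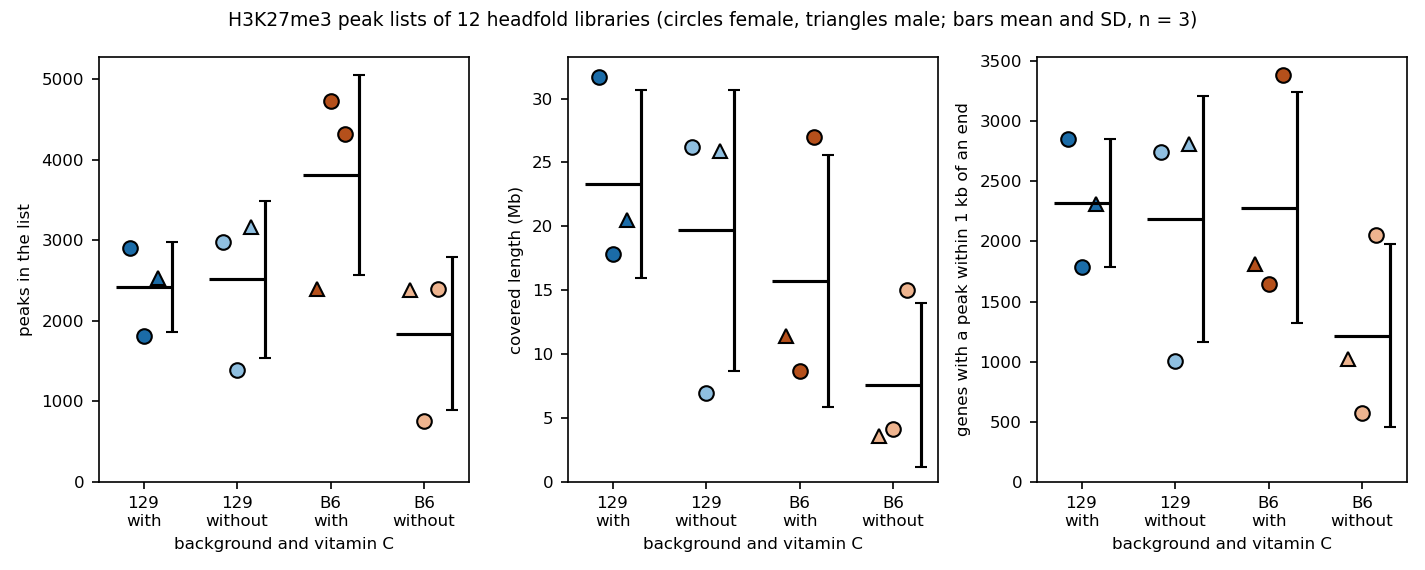
Peaks per list (left), covered length in Mb (middle) and genes with a peak within 1 kb of an end (right) for each of 12 libraries (circles female, triangles male), with the mean and SD of each group of 3. Libraries of one group spread widely, from 748 to 2395 peaks in B6 without vitamin C and from 1388 to 3171 in 129 without vitamin C.

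At single regions in B6, 85 regions were called in all 3 libraries with vitamin C and in 0 without, and 0 regions the other way. At gene level 58 genes followed this pattern. The 10 with the widest peaks were the clustered protocadherin genes Pcdhgc4 and Pcdhgc5, Troap, Ripk3 (a kinase of necroptosis), Gipc3, Tinagl1, Irx1 (an Iroquois patterning factor), Mei1, Rdh13 and Ckm (muscle creatine kinase). In 129 each of these 10 genes was marked in 2 or 3 libraries with vitamin C and in 2 or 3 without. Another split of the same 6 B6 libraries gave 189 such regions, and 10 splits are too few for any test below 0.05. The count was 4 when peaks had to cover at least 50% of a region, and 12, of which 7 were called only without vitamin C, when each list was held to its 748 strongest peaks by total signal. It was 3.56, 2.66 and 5.29 times as high without B6 with vitamin C replicate 1, without B6 with vitamin C replicate 2 and without B6 without vitamin C replicate 4, and 257 without both libraries of short peaks.

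In 129 only 7 regions separated the diets completely. The 4 called only with vitamin C lay at Shank3, a synaptic scaffold gene (chromosome 15, 89495896 to 89503766), at Nod1, an innate immune receptor gene (chromosome 6, 54941617 to 54946749), at the noncoding genes Gm31194 and Gm31317 (chromosome 11, 98293117 to 98300357), and in a stretch without annotated genes (chromosome 8, 120962106 to 120976089). The 3 called only without vitamin C were the array of 5S ribosomal RNA genes (chromosome 8, 123536023 to 123626858, 90.8 kb) and a pair of regions of an unplaced scaffold. By maximum signal within the lists that held them, the 4 lay at median percentiles of 28.9 to 39.3 and the 3 at 99.3 to 99.9. The lowest percentile of the 4 in any list was 3.15, at Shank3. The gene-level rule named Gas8, whose end overlaps the 5S array, as marked only without vitamin C, and Fcho1, Panx2 and Ino80e as marked only with it. Fcho1 lies at the edge of the 61.9 kb region that was called in all 12 libraries. The 5S array was called in 3 of 3 B6 libraries of either diet, so the difference was limited to 129. Leaving out one library in turn gave 16 and 28 regions without 129 with vitamin C replicates 1 and 2, and 13, 147 and 15 without 129 without vitamin C replicates 1, 2 and 3. Of these, 12 of the 16 and 142 of the 147 were called only without vitamin C, and in the other 3 cases 23 of the 28, 10 of the 13 and 12 of the 15 only with it. The count was 11 when peaks had to cover at least 50% of a region and 21 with equal lists, in both cases above that of B6 (4 and 12).

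Over both backgrounds, 0 of 3533 regions passed an adjusted p of 0.05 in the exact permutation test with Benjamini-Hochberg adjustment, and 1 had an unadjusted p below 0.05. This was the region at chromosome 8, 120962106 to 120976089 (14 kb), called in 5 libraries with vitamin C and 0 without (exact permutation p = 0.02). Its median percentile by maximum signal within the lists that held it was 28.9. With a smallest p of 0.005, regions can pass adjustment over this many regions only where many of them reach that value. Of 200 simulated regions that were all-or-none in both backgrounds, 0% were recovered after adjustment and 100% before it. Both shares follow from how the simulation was set up, and partial effects were not simulated. The count of 1 became 17 and 18 without 129 without vitamin C replicates 1 and 3, and 2, 12 and 4 without 129 with vitamin C replicates 1, 2 and 3. It became 5, 8 and 2 without B6 with vitamin C replicates 1, 2 and 4, and 2 and 4 without B6 without vitamin C replicates 1 and 4. The genes with the largest excess of marked libraries with vitamin C were Fcho1 and Panx2 (5 against 0), 2310011J03Rik (5 against 1) and Pcdhgc4, Troap, Ripk3, Tinagl1, Mei1 and Dlgap3 (6 against 2), with Chrnd at 4 against 0. In the other direction were Gas8 (6 without against 3 with), Nrp2, a semaphorin receptor gene, Mn1, Cebpb and Cpne5 (3 against 0), Tubb6 (4 against 1), Ccdc65 and Csf1 (2 against 0), and Pcdhgb1 and Zhx1 (3 against 1). Marked libraries were more numerous with vitamin C at 2623 genes and without it at 344, counts that were made on full lists of unequal length.

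Of the 16 gene lists, 0 passed the diet test after adjustment and 0 had an unadjusted p below 0.05 (exact permutation within background). The share of marked anterior neural plate and brain patterning genes was 87.3 ± 8.49% with and 75.5 ± 9.45% without vitamin C in 129 (SD, n = 3), and 77.5 ± 15.1% and 60.8 ± 17.7% in B6. The difference of -14.2 percentage points had the lowest p of the lists (exact permutation p = 0.095, adjusted p = 0.4). With equal lists it was -1.47 points (exact permutation p = 0.97). The lists of dorsal neural tube and neural crest genes (-15 points), ventral neural tube genes (-15.7), neurogenic genes (-12), endoderm genes (-11.9), placode and surface ectoderm genes (-10.4), heart and vascular factors (-7.97), neural tube closure genes (-7.58), mesoderm, somite and muscle genes (-7.33) and Hox genes (-6.41) had values of the same sign. Imprinted genes (-4.81), Polycomb subunits (-5.56), vitamin C transport and dependent enzymes (-1.04), DNA methylation enzymes (-1.19), germline genes (0) and housekeeping genes (0.556) differed by less. With equal lists the Hox genes were at -12.8 points, endoderm genes at -3.17, neural tube closure genes at -0.505, heart and vascular factors at 0 and mesoderm, somite and muscle genes at 0.667. Ventral neural tube genes were then at -13.7 points, dorsal neural tube and neural crest genes at -8.89, neurogenic genes at -6.48, placode genes at -5.56, Polycomb subunits at -1.67 and imprinted genes at -1.48. The counts of members below come from full lists of unequal length. On these, of 3876 genes marked in any library, 2623 were marked more often with vitamin C and 344 more often without. Within the anterior neural list 18 members were marked in fewer libraries without vitamin C, 0 in more and 16 in as many. The members that differed most there were Zic2 (4 libraries with and 1 without) and Otx2 (3 and 0), followed by 7 members with a difference of 2, among which Otx1 (6 and 4) and Sox2 (2 and 0) had the widest peaks. In the dorsal list the counts were 20, 1 and 9. The largest difference there was 2, shared by 8 members, of which Pax7 (5 and 3), Pax3 and Dlx5 (6 and 4) and Tfap2a (5 and 3) had the widest peaks. In the Hox list they were 13, 0 and 26, led by Hoxc8 and Hoxb2 (6 and 4). Shh, the floor plate signal, was marked in 6 libraries with and 3 without vitamin C, Lhx4 in 5 and 2, and the imprinted growth factor gene Igf2 in 6 and 3. Among Polycomb subunits 7 were marked in fewer libraries without vitamin C, 2 in more and 21 in as many. Pcgf1 and Pcgf5 were each marked in 5 with and 2 without, and Epop (1 and 3) and Pcgf3 (0 and 2) went the other way. Peak sets of embryos on the same diet were no more alike than those of embryos on different diets (mean Jaccard index 0.404 and 0.423 within background, one-sided exact permutation p = 0.74).

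The next comparison was of the B6 against the 129 background. A ribosomal RNA related sequence, Rn18s-rs5 with AY036118 (chromosome 17, 39841456 to 39848829), was called in 6 of 6 B6 libraries and 0 of 6 of 129. It was the only region with that pattern. Whether reads from other copies of ribosomal RNA sequence entered this call cannot be seen from the peak lists. Conversely 3 regions were called in 6 of 6 libraries of 129 and 0 of B6. They lay at LOC115488283 and Gm51421 (chromosome 14, 6036775 to 6040656), at Gm3715 and Gm5456 (chromosome 14, 7241891 to 7247362), and in a stretch without annotated genes (chromosome 10, 8547886 to 8551449). How well reads of each background aligned to mm10 at the regions named here cannot be seen from the peak lists. These regions were chosen after their values were seen. Their median percentiles by maximum signal within the lists that held them were 98.5 to 99.5, and the lowest in any list was 75.4, for the region at Gm3715 and Gm5456.

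By gene, those marked most often in 129 relative to B6 were LOC115488283 (6 against 0), Exoc3l2, Per1 (a circadian clock gene), Gm11127, Serinc2 and Zfp428 (5 against 0), and Sarm1, H2-T3, Mapt (encoding the microtubule protein tau) and Zfp316 (6 against 1). Those marked most often in B6 were Gm8909 (6 against 2), Gm39002 and Lars2 (5 against 1), Vipr2 and Vim (4 against 0; Vim encodes vimentin), Gas8 (6 against 3), Rtn4rl1 (4 against 1), Anxa4 (5 against 2), and Ephb1 and Tnfrsf13c (3 against 0). Gm8909, Gm11127 and H2-T3 lie in the class I major histocompatibility region of chromosome 17, whose near-identical copies can share reads, and the 0.421 kb peaks at Lars2 were far narrower than the others. Marked libraries were more numerous in 129 at 2215 genes and in B6 at 833, counts that were made on full lists of unequal covered length. Peak numbers did not separate the backgrounds (1.03-fold, exact permutation p = 0.91). The covered length was 11.6 ± 8.67 Mb in B6 and 21.5 ± 8.63 Mb in 129 (SD, n = 6), 0.471-fold on geometric means (exact permutation p = 0.07). Pairs of libraries within a background, pooled over 129 and B6, had a mean Jaccard index of 0.415, and pairs between backgrounds 0.351. Pairs of 129 lay above the mean between backgrounds (0.509 on the same diet and 0.53 on different diets). Pairs of B6 lay below it (0.299 and 0.315), so B6 peak sets were not more alike among themselves than with those of 129. The pooled difference was 0.0641 with a one-sided exact permutation p of 0.05. It passed the threshold in the same exact test with equal lists (0.0919, p = 0.025) and without 129 without vitamin C replicate 2 (0.0861, p = 0.035), B6 with vitamin C replicates 1 (0.0839, p = 0.04) and 4 (0.13, p = 0.015) or B6 without vitamin C replicate 4 (0.10, p = 0.035). It did not pass with the Jaccard index of regions (0.013, exact permutation p = 0.225) or without both libraries of short peaks (0.0602, p = 0.12). It fell as low as 0.0284 (exact permutation p = 0.135) without 129 without vitamin C replicate 1 and 0.0285 (p = 0.18) without 129 with vitamin C replicate 1. Without 129 without vitamin C replicate 3 it was 0.0306 (exact permutation p = 0.125), and without 129 with vitamin C replicates 2 and 3 it was 0.0467 (p = 0.11) and 0.0366 (p = 0.135). Library numbers ran with background, so background and library batch cannot be told apart.

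The last comparison was of female against male embryos, in which the X chromosome bears on the sex labels because the inactive X of females carries H3K27me3. The X chromosome made up 3.14 ± 3.28% of covered length in females (SD, n = 8) and 0.966 ± 0.361% in males (n = 4), a difference of 2.17 percentage points (exact permutation within background, two-sided, p = 0.284). Within 129 the difference was 1.5 points (p = 0.4) and within B6 2.84 points (p = 0.533), for which exact permutation cannot go below 0.0667. The X-linked genes marked in a larger share of female than male libraries were led by Frmpd3, Ptchd1 and Gpm6b (5 of 8 females and 0 of 4 males each). Bcor (a corepressor gene), H2al1b, H2al1c, Apln and Tenm1 followed with 4 females and 0 males, and Lonrf3 with 6 females and 1 male. Of the 8 females, B6 with vitamin C replicate 2 had the highest X share, 10.9%. Without it the difference between the sexes was 0.99 points, and with equal lists of all libraries 0.86 points.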

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

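Of the tests in this part, the one of weak peaks on the X chromosome was chosen after the result was seen. The X chromosome made up 10.9% of the covered length of B6 with vitamin C replicate 2, a female. This lay far from the other 5 libraries of B6 (gap over range 0.859) and from the other 7 females (0.751), in both cases above Dixon's 95% critical value. Over 16 groups of values there were 2 such distances, both from the X share of this library. Chance gives about 1 in 20 independent groups, but these groups share libraries and the 2 distances rest on 1 value. The list held 681 peaks on the X chromosome, in 18 of 18 stretches of 10 Mb.

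Weak peaks spread evenly over the whole genome were argued against as the source of this X share. Of the 893 peaks that no other list overlapped, 58.8% lay on the X chromosome, 9.04 times its share of the genome length. This follows in part from the X share that was flagged, because no other list held more than 93 peaks on the X chromosome. Weak peaks concentrated on the X chromosome were not tested. The inactive X of females could be the source. The list's X peaks recurred in other females at a mean 0.126 ± 0.0623 of the rate of its autosomal peaks and in males at 0.0666 ± 0.0228 (SD). The difference was 0.0589 (exact permutation p = 0.115), which does not decide it. Here sex labels were permuted over all other libraries without regard to background (330 relabellings). Of the 2 libraries with short peaks this one had a median width of 1.41 kb, and the other, B6 without vitamin C replicate 1, a male, had 1.32 kb and an X share of 1.4%.

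Peaks also lay on the Y chromosome, which no comparison of the report singles out, and on unplaced scaffolds, of which the report names a pair of regions. Female lists together held 15 peaks on the Y chromosome, 14 of them above 90 Mb. Of the 15, 9 were in the list of B6 with vitamin C replicate 2, and each other female list held at most 1. Over all lists 54 peaks lay on 11 unplaced scaffolds, 27 of them on a single scaffold. No explanation was tested for either.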

How the results depend on the processing

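Of the tests in this part, omission of both libraries of short peaks and, for marked genes, peaks anywhere in the gene and peaks at both gene ends were chosen after the lists had been seen. The diet difference kept its sign and its side of the threshold under all alternatives run for peak number (22 settings, -0.74 to -0.31 with each library left out), covered length (19, -1.14 to -0.49) and marked genes (20, -0.85 to -0.37, and -0.21 with equal lists), and the X share by sex did so in 16 settings, with 0.86 points with equal lists and 1.21 without both libraries of short peaks. Within B6 the difference in peak number kept its sign in 7 settings (-1.48 to -0.62 with each library left out), where no p under 0.05 is possible. Consecutive library numbers as a replicate block gave -0.59 for peaks (exact permutation p = 0.219), -0.81 for covered length (p = 0.0938) and -0.61 for marked genes (p = 0.0938). The deviations of these pairs correlated at 0.18, 0.35 and 0.11 in 129 and 0.08, -0.01 and 0.03 in B6 (mean of other pairs across diets -0.06). Not all pairs were above 0.1, so the numbers were not taken to pair the samples. The block changed no call.

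For the results below that changed, the cause was not tested. The log2 difference in peaks by diet in 129 ranged from -0.22 to 0.38 and turned positive without 129 with vitamin C replicates 1 (0.14) and 3 (0.0409) and without 129 without vitamin C replicate 2 (0.38). The difference of diet effects ranged from 0.61 without B6 without vitamin C replicate 2 to 1.55 without 129 without vitamin C replicate 2, the latter past the threshold. The difference in peaks between backgrounds was -0.0908 with peaks of at least 1 kb, -0.14 with peaks joined and -0.19 without both libraries of short peaks. With single libraries left out it ranged from -0.15 to 0.32, and was negative without 129 without vitamin C replicate 2 (-0.15), 129 with vitamin C replicate 2 (-0.0553), B6 without vitamin C replicates 1 (-0.0957) and 4 (-0.0983) and B6 with vitamin C replicates 2 (-0.0499) and 4 (-0.0175). Similarity by diet ranged from -0.0399 to 0.0296 and was positive without 129 without vitamin C replicates 1 (0.00824) and 3 (0.00571) and B6 without vitamin C replicate 4 (0.0296). Similarity by background was 0.0919 with equal lists and 0.0284 to 0.13 with single libraries left out. The mesoderm list's difference by diet was 0.67 points with equal lists, and that of the anterior neural list -1.47.

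Counts of regions moved as well. All-or-none regions by diet in 129 (7) were 11 at 50% cover, 21 with equal lists and 10 to 147 with single libraries left out, highest without 129 without vitamin C replicate 2. Those in B6 (85) were 4, 12 and 87 to 450, highest without B6 without vitamin C replicate 4, and 257 without both libraries of short peaks. With a library left out fewer libraries need to concur, which by itself raises these counts. Regions at unadjusted p under 0.05 over both backgrounds (1) were 2, 6, 2 without both libraries of short peaks, and 1 to 18 with single libraries left out, highest without 129 without vitamin C replicate 3. The count after Benjamini-Hochberg adjustment was 0 in each of these settings.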

Other observations

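Of the tests in this part, those of the 5S array and of a diet effect shared by both backgrounds were chosen after the result was seen, as were the groups of gene symbols. Gene families of signalling and patterning stood out among genes marked in at least 10 libraries when symbols were grouped by their letters, with 9 of 270 groups of at least 10 genes at an adjusted p under 0.05 by Fisher's exact test. Hoxc and Hoxd, with 9 genes each, were below that size and not tested. Besides Hoxa (11 of 11) and Hoxb (10 of 10) the groups were Wnt (13 of 19), Nkx (11 of 14), Tbx (8 of 13), Sox (8 of 19), Pou (7 of 16), Bmp (5 of 12) and Prdm (5 of 14). Every one of the 19 Wnt genes was marked in at least 1 library. Fgf genes (5 of 22) were not among them.

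Most peaks of each list overlapped the list with the largest covered length. That list, 129 with vitamin C replicate 1, overlapped 71.4% to 99.1% of the peaks of the others by at least 1 bp, lowest for B6 with vitamin C replicate 4. The share was 78.4% for B6 without vitamin C replicate 1, the list of smallest covered length (3.58 Mb). For 129 without vitamin C replicate 1 (26.2 Mb) it was 91%. The median width of regions was 4.23 kb for those called in 2 libraries and 17.3 kb for those called in 12. Regions were merged from the peaks of all lists, so width and number of libraries are tied by how regions were made. A region of 117.6 kb without annotated genes (chromosome 6, 114521599 to 114639204) held the highest total signal of 2 lists of 129 and was called in 6 of 6 libraries of 129 and 3 of 6 of B6.

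The array of 5S ribosomal RNA genes (chromosome 8, 123536023 to 123626858) was called in 9 libraries and held the highest total signal in 9 lists, but was called in 0 of 3 lists of 129 with vitamin C. Weak signal near the calling threshold was argued against for the 9 lists that held the array. In each of them its strongest peak lay at percentile 96.9 or higher by maximum signal. Its signal in the 3 lists without the call cannot be seen from the peak lists. A diet effect shared by both backgrounds was argued against too, because 3 of 3 B6 lists with vitamin C held it. A control library or filter that differs between groups could account for the absence and cannot be told apart from a diet effect in 129. The array holds 48 ribosomal RNA genes, and the lists do not show how reads that match several of them were placed. Besides the array, 2 of 128 strong regions, both on a single unplaced scaffold, were all-or-none by diet in 129, against at most 1 in other splits, and the IgG libraries were not analysed here.

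The 85 regions called only with vitamin C in B6 could reflect list length and signal height. Their median percentile by total signal within the 3 lists that held them was 41, and below 50 in 2 of the 3 lists taken singly. A diet effect shared by both backgrounds was not decided, because in 129 the same regions were called in 0.0824 more libraries of 3 with vitamin C than without (SD over relabellings 0.772, exact permutation p = 0.8). Embryos of a single pregnancy cannot be told apart from diet, because the group had 1 pregnancy code. A diet effect in B6 alone stays open and was not tested further.

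Other splits of the same libraries were counted for each set of regions. In B6, 3 of 10 splits, the real one included, gave at least 85 regions and the highest other gave 189 (5.35% of the 3533 regions). In 129, 6 of 10 gave at least 7 and the highest other split took in 6.82% of the regions. Splits of 3 against 3 are too few for a share under 0.05. The highest other splits parted libraries with many marked genes from those with few, and point to a structure of the samples apart from diet. Over both backgrounds, 41 of 100 splits gave at least 1 region at unadjusted p under 0.05, with 3.42% of the regions in the highest other, so chance was not excluded.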
